A study of Mus musculus with 5 samples.

How the data were processed

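Total RNA was isolated from mouse thyroid glands and made into stranded libraries after the kit for total RNA, per the labels' protocols, and the submitters' processing notes name HISAT2, StringTie and DESeq2, without versions, and the genome build mm10. The roles of these tools, and whether counting used strand, are not given in the sources used here. The authors deposited whole-number read counts per gene and FPKM values in 2 sheets that hold the same 16413 genes, with 100% of the counts and of the FPKM values equal between them. Each listed gene had a count of at least 1 in every library, so genes with a count of 0 in any library were not analysed here. Per the file headers, a further set of deposited columns holds normalized log2 values, which matched quantile-normalized log2(FPKM + 1) to within 0.001. The authors' deposited table also gives fold changes, p-values and adjusted p-values for the diets. The fold is signed as chow over high fat diet, and its p-values equal those of an unequal-variance test on the normalized values for 16410 of 16412 genes (tolerance 1e-06). There, 0 genes had an adjusted p under 0.05, the lowest was 0.971, and 636 genes had an unadjusted p under 0.05, 253 higher and 383 lower on the high fat diet, where chance gives 821. The columns spell high fat diet with a different middle letter, and were matched to the samples by treatment and number. A further 3 columns of per-sample counts belong to no sample here and were not used in any step.

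Groups were taken from the diet in the labels: 2 chow and 3 high fat diet libraries, with 43494747 to 52663677 counts each. The deposited counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr and a quasi-likelihood fit with robust shrinkage, on the diet alone. The filter removed 648 genes and left 15765, and p-values were adjusted by Benjamini-Hochberg over these with a threshold of 0.05. The common biological coefficient of variation was 18.8%. CPM are counts scaled by TMM-adjusted library size, standard errors come from the same fit, and the 95% intervals cover the log2 fold change. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 33 lists with at least 3 measured members. Beside it stand camera with an estimated correlation and fry, which asks whether a list moves 1 way without comparing it with other genes: with either, 0 lists passed. With an estimated correlation, camera takes its degrees of freedom from the libraries and not from the genes. With so few libraries it can miss lists that do move, so a call lost there does not settle a list. The design, the 36 gene lists, the rule for named genes and most alternatives were written before the data were examined.

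The named genes were Adm2 and the adrenomedullin list, Tg, Slc5a5, Tshr and Braf, whatever their values, then up to 12 genes per direction of largest change past the threshold. Since fewer than 5 genes passed in either direction, the 10 of smallest p in each direction were named as not passing, and for each list up to 4 members of smallest p; names given beyond this rule are said to be chosen after their values were seen. Some genes that this rule names are not reported here, though they stay in every test and count. Gene positions come from the GENCODE annotation of mm10. The edgeR and DESeq2 steps were tested on simulated counts for 15765 genes with the real means and library sizes, and with 200 genes changed. Each gene's dispersion was drawn around the trend that edgeR fitted to the real libraries and was the same in every library. Libraries that stand apart were therefore not simulated. The changed genes were drawn from those above a bound on mean CPM, so changes in genes of low expression were not covered. In this comparison of high fat diet against chow, edgeR recovered 42% of 2-fold and 95% of 4-fold changes and called 149 genes, 12 of them unchanged. DESeq2 recovered 78% and 100% and called 261 genes, 83 of them unchanged. With no gene changed, edgeR called 0 and DESeq2 called 35. Each of these simulated sets was drawn a single time. Alternatives were RLE and upper-quartile factors, no filter and a stricter filter (at least 1 CPM in all libraries of a group), DESeq2 1.42.0, limma-voom, a fit without robust shrinkage, and leaving out each library in turn. An adjusted p threshold of 0.10, limma on the deposited normalized values and the adrenomedullin list without Adm2 were added after the data were seen.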

Results

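The transcriptome of the thyroid gland was profiled in mice carrying a conditional oncogenic Braf allele switched on in thyroid cells by tamoxifen, given for 1 week from 8 weeks of age. The animals ate chow or a high fat diet for 12 weeks, from 10 to 22 weeks of age, and the libraries were made from total RNA of the thyroid. The chow group had 2 libraries (replicates 2 and 8) and the high fat diet group had 3 (replicates 2, 9 and 10), and every animal carried the mutation, so the only comparison was between the diets. Total counts over genes were 43494747 and 43774210 in the chow libraries and 52663677, 49157018 and 47307084 in the high fat diet libraries. Thyroglobulin (Tg), the scaffold protein of thyroid hormone, alone took 18.7% and 22.1% of the counts in the chow libraries and 17.1%, 14.9% and 10.9% in the high fat diet libraries. The labels number the samples but do not say that each number is a separate animal, so the p-values measure the spread between these samples.

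The series is about adrenomedullin 2 (Adm2, gene ID 223780), a secreted peptide of the calcitonin family, in thyroid cancer under nutrient excess, so its level was examined first. Adm2 stood at 2.76 ± 0.457 CPM (SD, n = 2) on chow and 11.4 ± 2.61 CPM (SD, n = 3) on the high fat diet, 4.12 times as high, and each high fat diet library lay above both chow libraries. The counts were 133 and 100 on chow and 508, 498 and 727 on the high fat diet. The gene spans chromosome 15 from 89322720 to 89324731 on the plus strand of mm10 and has 3 annotated exons. The log2 fold change was 2.04 with a standard error of 0.24 and a 95% interval from 1.49 to 2.60. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0731 over the 15765 genes tested, above the threshold of 0.05, and 0.00014 adjusted over the list alone. Because the series title names Adm2, which may have been picked from these samples, the value adjusted over the list alone is not independent evidence. DESeq2 gave a log2 fold change of 2.04 with an adjusted p of 3.39e-11, while in the other alternatives the adjusted p ran from 0.0528 to 0.316. The authors' deposited table lists a fold of 3.04 with an adjusted p of 0.971. It rests on normalized log2(FPKM + 1) values, where the 1 that is added shrinks the fold of a low gene.

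None of the other genes of the adrenomedullin system passed over all genes in edgeR either. Ramp1, an accessory protein of the shared receptor, had a log2 fold change of 0.58 with a standard error of 0.19, the scavenging receptor Ackr3 had 0.35, Ramp3 had 0.39 and Ramp2 had 0.14. The receptor gene Calcrl was level at 88.3 ± 16.9 CPM (SD, n = 2) on chow and 89.5 ± 15.1 CPM (SD, n = 3) on the high fat diet, and the related peptide Adm had a log2 fold change of -0.14. As a list of 7 measured members, 6 of them above 0, with a median log2 fold change of 0.35, the adrenomedullin system rose by camera (adjusted p = 7.5e-05), with 1 member higher and 0 lower when adjusted over the list alone. It did not pass in a second form of the test (adjusted p = 0.573 with an estimated correlation), and without Adm2 the remaining members gave an adjusted p of 0.081.

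**Figure D1:**
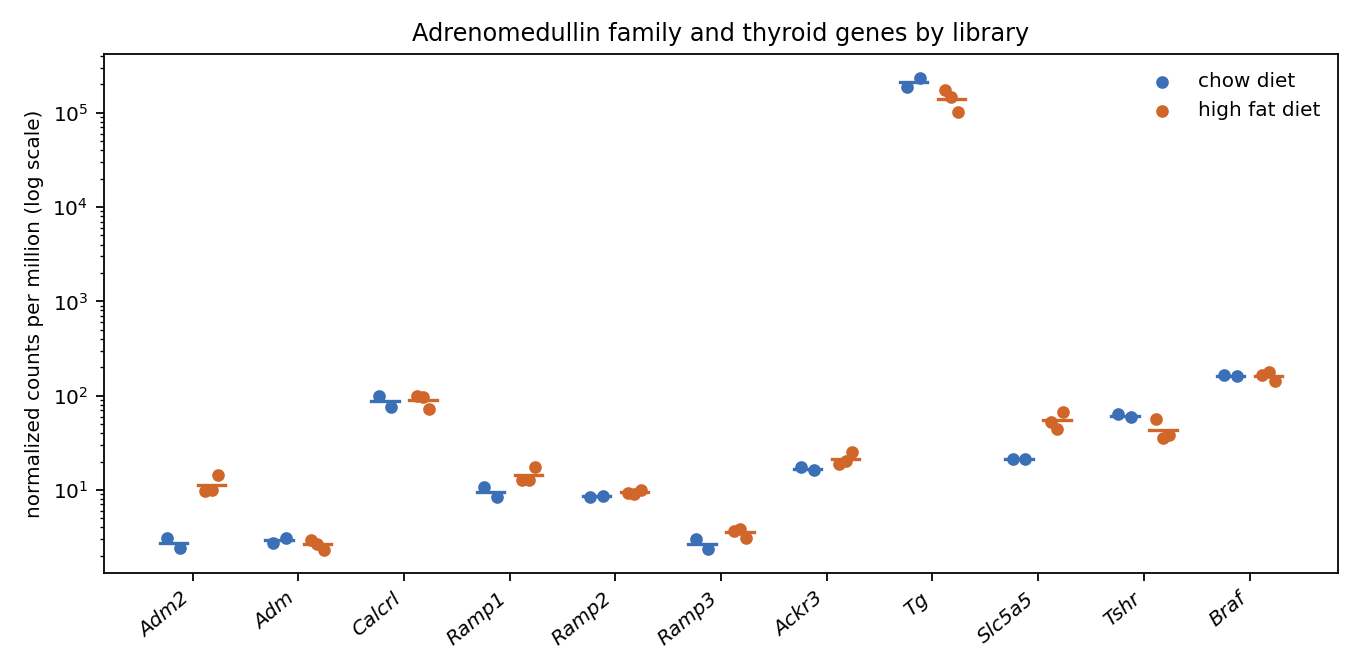
Normalized CPM (log axis) of adrenomedullin system genes, thyroid genes and Braf in each of the 2 chow and 3 high fat diet libraries, with points for libraries and short lines for group means. Adm2 lies between 9.82 and 14.4 CPM in the high fat diet libraries, above 3.08 and 2.43 CPM in the chow libraries.

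Among thyroid differentiation genes, those for iodide handling were higher and the hormone scaffold was lower on the high fat diet. Slc5a5, the sodium iodide symporter, was at 21.3 ± 0.204 CPM (SD, n = 2) on chow and 54.6 ± 11.0 CPM (SD, n = 3) on the high fat diet, a log2 fold change of 1.36 with a standard error of 0.17. The anion exchanger Slc26a4 (pendrin) had a log2 fold change of 0.78, and the transcription factor Foxe1 had 0.78. These 3 passed when adjusted over the list alone, where 3 of the 18 members were higher and 1 was lower, and 0 members passed over all genes. Tg averaged 212070 ± 33296 CPM (SD, n = 2) on chow and 140740 ± 35871 CPM (SD, n = 3) on the high fat diet, a log2 fold change of -0.59 that did not pass (edgeR adjusted p = 0.91). The thyrotropin receptor gene Tshr had -0.50 and Braf itself -0.01, neither of which passed. As a list, thyroid differentiation did not change by camera (adjusted p = 0.824), with 7 members above 0 and 11 below.

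Over all genes, 0 were higher and 0 lower at an adjusted p under 0.05 in edgeR, against 49 higher and 47 lower in DESeq2 and 0 and 0 in limma-voom. At an unadjusted p under 0.05 edgeR gave 855 genes, 465 higher and 390 lower, where chance gives 788. Genes among the 10 of smallest p in each direction are named here although they did not pass. Besides Adm2 and Slc5a5, the higher ones included Sumo3, a ubiquitin-like modifier, at 24.7 ± 4.56 CPM (SD, n = 2) on chow and 61.8 ± 2.41 CPM (SD, n = 3) on the high fat diet, and Ywhaz, an adaptor for phosphorylated proteins, at 236 ± 30.2 and 486.0 ± 19.0 CPM. The predicted gene Gm6710 had a log2 fold change of 1.52, the secreted factor Angptl7 had 1.41, the NF-kB inhibitor Tnfaip3 had 0.76, the clock repressor Per2 had 0.72 and the monooxygenase-like Moxd1 had 0.74. Gm6710 is uncertain, since counting can split the reads of predicted genes with near-identical copies, and the same holds for Ywhaz and Sumo3, which have relatives of similar sequence. Among those relatives, looked at after the values were seen, Sumo2 had 0.13, and the Ywha genes ran from -0.15 for Ywhaq to 0.10 for Ywhag, with the related Sfn at 0.48, and none passed in edgeR.

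The lower genes were led by Actc1, cardiac muscle actin, which was at 11.0 ± 5.52 CPM (SD, n = 2) on chow and 1.73 ± 0.218 CPM (SD, n = 3) on the high fat diet, a log2 fold change of -2.67. Cyp2e1, a microsomal oxidase of ethanol and ketones, was at 17.5 ± 4.90 CPM on chow and 2.81 ± 0.971 CPM on the high fat diet, a log2 fold change of -2.64. Myo3b, an actin motor, had -1.09, the complement component C7 had -1.37, Trank1 had -0.93 and Pde7b, a cyclic AMP phosphodiesterase, had -0.85. Tenm3, Fat2, Slc43a2 and Rp2 lay between -0.66 and -0.62. In edgeR the lowest adjusted p was 0.0731, that of Adm2, Sumo3, Ywhaz, Slc5a5, Actc1, Myo3b and Cyp2e1 among others, and 6 higher and 4 lower genes had an adjusted p under 0.10. DESeq2 called all 10 of these, but on a single simulated set of unchanged data of this size DESeq2 made 35 calls and edgeR 0. How strong those 35 calls were was not examined, so their number does not settle these 10 genes. With 1 library left out, edgeR gave 2 higher and 3 lower genes without chow replicate 8 (Sumo3 and Actc1 among them), 0 and 2 without chow replicate 2, and 1 and 2 without high fat diet replicate 2, and DESeq2 gave 36 to 74 higher and 13 to 55 lower, the lowest counts without chow replicate 8.

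**Figure D2:**
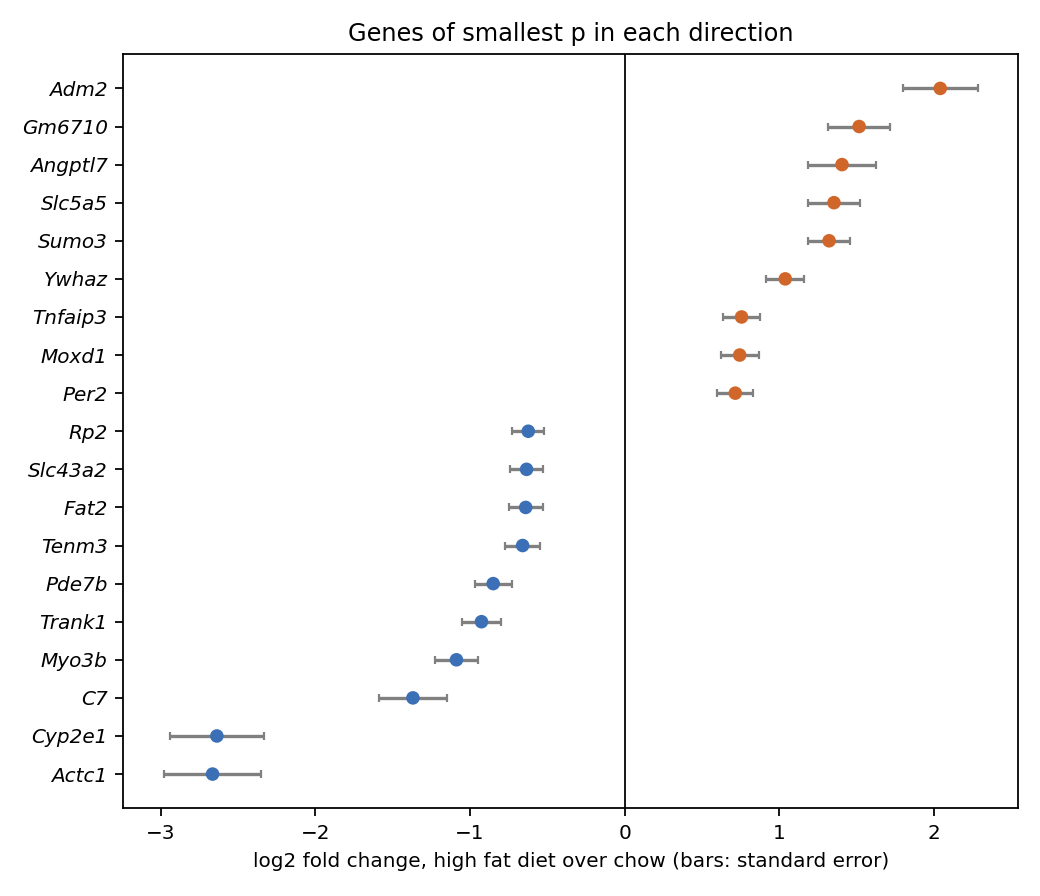
Log2 fold change (high fat diet over chow, edgeR) with its standard error for genes among the 10 of smallest p in each direction, orange where higher and blue where lower on the high fat diet. Values run from -2.67 for Actc1 to 2.04 for Adm2, and the lowest adjusted p was 0.0731.

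Gene lists for growth signalling and inflammation lay higher on the high fat diet. Of 18 targets of the MAPK pathway, the pathway that mutant Braf drives, 16 were above 0, with a median log2 fold change of 0.24. Dusp6, a phosphatase that restrains ERK, had 0.33, the transcription factor gene Etv4 had 0.50 and Ier3 had 0.51. The ERK-pathway inhibitor Spry1 had -0.28. Leaving out 1 library, Etv4 ran from 0.31 to 0.64, Ier3 from 0.24 to 0.66 and Spry1 from -0.39 to -0.16. This list rose by camera (adjusted p = 0.00422; adjusted p = 0.633 with an estimated correlation), with 0 members passing when adjusted over the list alone. The markers of papillary thyroid cancer also rose (camera adjusted p = 0.00988; adjusted p = 0.573 with an estimated correlation), with 12 of 15 above 0. The cell surface mucin Muc1 was at 32.4 ± 0.268 CPM (SD, n = 2) on chow and 58.9 ± 10.4 CPM (SD, n = 3) on the high fat diet, and it was the 1 member to pass over the list alone, while Sdc4 had a log2 fold change of 0.51, Fn1 0.63 (0.20 without high fat diet replicate 10) and Hmga2 -0.23. High fat diet replicate 10 had the highest median of both lists, as it had of the airway epithelium list (1.04, the other libraries from -0.546 to 0.214), and Muc1 was highest there at 68.7 CPM. Without this library their adjusted p was 0.0783 and their means went from 0.29 to 0.074 and from 0.23 to 0.113. Without chow replicate 2 the adjusted p was 0.357 for MAPK targets and 0.073 for the cancer markers, with means of 0.237 and 0.23.

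Lists of inflammatory and interferon genes also lay higher on the high fat diet. Tnfaip3 was at 17.0 ± 0.289 CPM (SD, n = 2) on chow and 28.8 ± 1.78 CPM (SD, n = 3) on the high fat diet. It passed over its list alone. The adhesion molecule Icam1 had a log2 fold change of 0.32, the chemokine Cxcl1 0.56 and the NF-kB brake Nfkbia -0.35. Leaving out 1 library, Cxcl1 ran from 0.30 to 0.73 and Nfkbia from -0.58 to -0.071. The inflammatory list rose (camera adjusted p = 0.00988; adjusted p = 0.633 with an estimated correlation), and so did the interferon list (camera adjusted p = 0.00217; adjusted p = 0.633 with an estimated correlation). In the latter Ifit3 had 0.57, Oas1a 0.44, Ifit2 0.37 and Ifit1 0.43. The immediate early list rose as well (camera adjusted p = 0.0102; adjusted p = 0.573 with an estimated correlation), where Junb had 0.63 and passed over the list alone, and Ier2 had 0.43, Klf4 0.31 and Fosb 0.77. The insulin, IGF and leptin signalling list rose (camera adjusted p = 0.0189; adjusted p = 0.607 with an estimated correlation), and Socs3, an inhibitor of leptin and cytokine signalling, passed over the list alone at 0.65, with Igfbp3 at 0.33, Irs2 at 0.21 and Igfbp5 at 0.25. Chow replicate 8 had the lowest median of these 4 lists, and without it their adjusted p lay at 0.335, 0.859, 0.191 and 0.495, in the order given. Their means were then 0.188, 0.051, 0.21 and 0.067, against 0.36, 0.31, 0.27 and 0.15 with all libraries. The macrophage median was also lowest in chow replicate 8 (-0.227) and highest in high fat diet replicate 10 (0.235). The neutrophil median was 1.58 in the latter. Without high fat diet replicate 10, which had their highest median, the inflammatory, immediate early and insulin lists had an adjusted p of 0.283, 0.0515 and 0.0515 and means of -0.008, 0.195 and 0.121. The interferon list kept its call with a mean of 0.172. The insulin list was also lost without high fat diet replicate 9, at 0.0892 with a mean of 0.136.

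Adipocyte and lipid synthesis genes lay lower on the high fat diet. Of 13 white adipocyte markers, 11 were below 0, with a median log2 fold change of -0.34. The lipid droplet gene Cidec was at 9.72 ± 1.92 CPM (SD, n = 2) on chow and 4.63 ± 0.797 CPM (SD, n = 3) on the high fat diet, adipsin (Cfd) at 44.1 ± 6.30 and 16.3 ± 5.97 CPM, and perilipin (Plin1) at 5.95 ± 0.915 and 2.86 ± 0.855 CPM, and these 3 passed over the list alone. Resistin (Retn) had a log2 fold change of -1.12, and leptin (Lep) went the other way with 0.77. The list fell by camera (adjusted p = 5.02e-09; adjusted p = 0.573 with an estimated correlation) and kept its call in each of the 5 fits that left out 1 library, with a mean log2 fold change of -0.48, or -0.318 without high fat diet replicate 10, the library with the lowest median. Fatty acid synthesis fell too (camera adjusted p = 0.0188; adjusted p = 0.573 with an estimated correlation), with 7 of 13 members below 0 and 6 above. Thrsp, a lipogenic regulator, was at 8.84 ± 2.71 CPM on chow and 3.76 ± 0.563 CPM on the high fat diet, the 1 member to pass over the list alone. Dgat2 had -0.53, Mlxipl -1.07 and Elovl6 -0.49, while the fatty acid synthase Fasn was at 0.35 and the citrate lyase Acly at 0.15. Cholesterol synthesis fell (camera adjusted p = 0.00988; adjusted p = 0.633 with an estimated correlation), with 12 of 15 members below 0, among them Stard4 at -0.39, Insig1 at -0.27 and Fdft1 at -0.26. Without chow replicate 8 the adjusted p was 0.339 for fatty acid synthesis, with a mean of -0.15 against -0.22 with all libraries. For cholesterol synthesis it was 0.284, with a mean of -0.086 against -0.145. Fatty acid synthesis was also lost without high fat diet replicate 9 (0.113, mean -0.199) and in limma-voom (0.0719, mean -0.23). Cholesterol synthesis was also lost without high fat diet replicate 2 (0.137, mean -0.092).

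Markers of other tissues and cell types also differed between the diets. All 10 airway epithelium genes were above 0, with a median log2 fold change of 0.89. The ciliated cell gene Tppp3 had 0.63 and passed over the list alone. The secreted proteins Bpifb1 and Bpifa1 had 1.53 and 0.80, and Dnah5, a motor of cilia, had 0.51. Leaving out 1 library, Bpifa1 ran from 0.47 to 1.06 and Dnah5 from 0.23 to 0.72. The list rose by camera (adjusted p = 1.53e-06; adjusted p = 0.573 with an estimated correlation). High fat diet replicate 10 held 4638 CPM of the airway mucin Muc5b, against 159 CPM in the next library, and without this library the list's mean log2 fold change went from 1.27 to 0.49 while its call was kept. Cartilage genes rose (camera adjusted p = 0.00306, or 0.573 with an estimated correlation). All 6 measured ones were above 0, with a mean of 0.99 (0.594 without high fat diet replicate 10). With the stricter filter the mean was 0.476 and the call was kept. The list members Col2a1, Matn1, Matn3 and Col9a2 were not measured. Acan, chosen after its value was seen, had 3.36, with 9.63 CPM in high fat diet replicate 10 and at most 1.12 CPM elsewhere. Col9a1 stood at 0.33, Comp at 0.39, Chad at 0.70 and Cytl1 at 0.78. Leaving out 1 library, Chad ran from 0.44 to 0.98 and Cytl1 from 0.39 to 1.10. Among endothelial genes 9 of 10 were above 0, with Plvap at 0.25, Kdr at 0.30, Tek at 0.34 and Cdh5 at 0.19. Leaving out 1 library, Tek ran from 0.14 to 0.58. The endothelial list rose by camera (adjusted p = 0.016, or 0.633 with an estimated correlation). That call was lost without chow replicate 8 (adjusted p = 0.506), where the mean went from 0.16 to 0.052 and Cdh5 to 0.0071. It was also lost without high fat diet replicate 2 (0.0678, mean 0.16) and without high fat diet replicate 9 (0.278, mean 0.098).

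**Figure D3:**
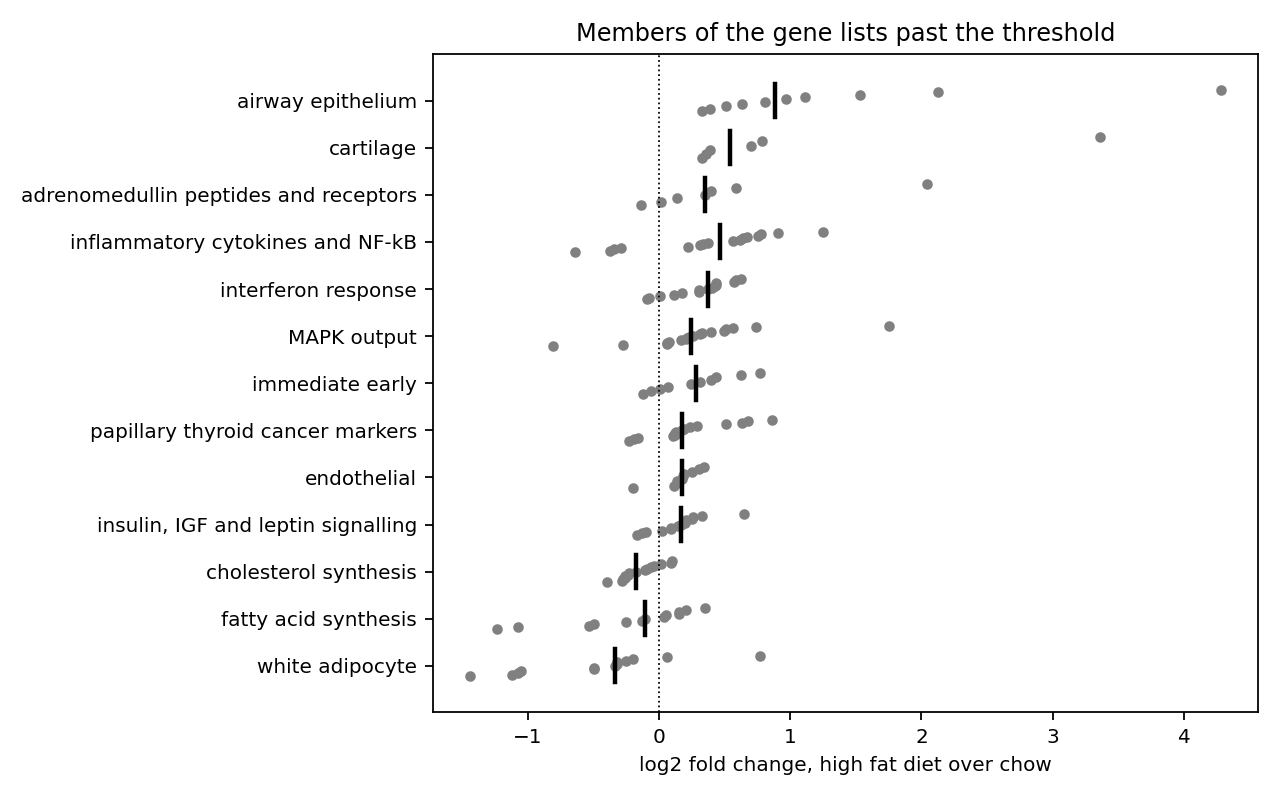
Log2 fold change (high fat diet over chow) of each measured member of the 13 gene lists that passed camera at an adjusted p under 0.05, with grey points for genes and black bars for list medians. White adipocyte, fatty acid synthesis and cholesterol synthesis lists have medians of -0.34, -0.10 and -0.17, and the airway list has a median of 0.89.

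Besides thyroid differentiation, 19 of the 33 lists tested did not pass with all 5 libraries, though 10 of them passed in at least 1 of the fits that left out a library. ER chaperones (camera adjusted p = 0.984; Xbp1 at 0.18) and the integrated stress response (0.306; Slc7a11 at 0.24) were near level, as were cell cycle genes (0.984; Mcm3 at 0.31) and the cyclic AMP response (0.211; Areg at 0.46). In metabolism, fatty acid oxidation gave 0.401 with Fabp3 at 1.28, oxidative phosphorylation 0.984 with Cox6a1 at 0.42, glycolysis and hypoxia 0.211 with Ldha at 0.29, and brown adipocyte markers 0.57 with Cidea at -0.80. Among stromal and immune cells the values were 0.596 for fibroblast and matrix (Acta2 at 0.55), 0.984 for epithelial to mesenchymal transition (Itgb6 at -0.30), 0.101 for macrophage (Fcgr1 at 0.49), 0.984 for neutrophil (Cxcr2 at 0.76), 0.984 for B and plasma cell (Mzb1 at -1.09) and 0.211 for T and NK cell (Cd3e at -0.58). C cell markers gave 0.101, and Calcb, a calcitonin family peptide, passed over the list alone with 1.00. Skeletal muscle gave 0.372 (Myh8 at -2.18), squamous epithelium 0.606 (Krt14 at -0.90), peripheral nerve 0.506 (Mbp at -0.36) and erythroid 0.716 (Hba-a1 at 3.80, from high fat diet replicate 10). The median, the mean and the test differed in sign for epithelial to mesenchymal transition, brown adipocyte, oxidative phosphorylation, B and plasma cell, and squamous epithelium. Thymocyte and parathyroid lists had 2 measured members each and were not tested, with mean log2 fold changes of -0.20 and -0.23. Myh8, Hba-a1 and Cxcr2 rest on single libraries: Myh8 was at 0.58 without chow replicate 2, and without high fat diet replicate 10 Hba-a1 was at -0.53, Cxcr2 at -0.70 and the neutrophil list's mean at -0.869 (camera adjusted p = 0.000557).

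Libraries did not group by diet. Spearman correlations of log2 CPM across genes, which are not independent replicates, were 0.991 between the chow libraries, 0.993 between high fat diet replicates 2 and 9, and also 0.993 between chow replicate 2 and high fat diet replicate 9. High fat diet replicate 10 was the most distant, at 0.981 to 0.986 from the others. The first principal component held 41.8% of the variance and set this library (49.9) apart from the rest (-16.4 to -4.6). The second held 24.4% and set chow replicate 8 apart (-36.7), the library with the lowest skeletal muscle median: Acta1 stood at 68.6 CPM there and 278 CPM in chow replicate 2. No library was a duplicate of another: counts of a duplicate would differ by counting noise alone, and the lowest chi-square of a pair was 39.8 per degree of freedom. All 5 libraries carried Y-linked transcripts, with Ddx3y between 105 and 137 CPM, and Xist stayed at or under 0.618 CPM. Genes whose groups did not overlap were 20.8% of those tested, where chance gives 20% for 2 libraries against 3.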

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

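The threshold of 0.10, limma on the deposited normalized values and the adrenomedullin list without Adm2 were tests chosen only after the data were seen. With edgeR, RLE factors, upper-quartile factors, no filter, the stricter filter and no robust shrinkage each gave 0 higher and 0 lower genes, as did limma-voom. DESeq2 gave 49 higher and 47 lower genes and an Adm2 log2 fold change of 2.04 (adjusted p = 3.39e-11), and the cause was not tested. Across the other alternatives that were set before the data were examined Adm2 kept its direction, with an adjusted p from 0.0528 to 0.316 and a log2 fold change from 1.84 (without high fat diet replicate 10) to 2.22 (without chow replicate 2). The threshold of 0.10 gave 6 higher and 4 lower genes, limma on the deposited values gave 0 and 0 with 1.60 for Adm2 (adjusted p = 0.13), and the list without Adm2 lost its call (mean 0.225, adjusted p = 0.081). Leaving out each library in turn gave 0 to 2 higher and 0 to 3 lower genes, with fewer libraries in each fit. The genes were Amd1 and Mcfd2 without chow replicate 2; Sumo3, Actc1, Bmf, Gm14434 and Myh8 without chow replicate 8; and Fam46a, Gtf2a1 and Pou2f1 without high fat diet replicate 2. With 1 chow library left, the lone sample is assumed to vary like the other groups. Of 1472 values of genes under alternatives, 1458 kept their sign. The 14 that did not belong to genes whose values, leaving out 1 library, ran from -0.075 to 0.073 for Braf, -3.07 to 0.58 for Myh8, -0.17 to 0.11 for Hspe1 (-0.012 with limma-voom), -0.16 to 0.22 for Calcrl, -0.051 to 0.26 for Nr1d2, -0.70 to 1.21 for Cxcr2, -0.53 to 5.20 for Hba-a1, -0.060 to 0.085 for Dnajb1 and -0.15 to 0.57 for Sftpa1. For lists, camera with an estimated correlation gave 0 higher and 0 lower and fry gave 0 and 0. With an estimated correlation camera also has far fewer degrees of freedom, those left by so few libraries, so these lost calls do not settle the lists. How much each difference cost was not tested. The estimate was -0.06 for the adrenomedullin list and 0.014 for fatty acid synthesis, against the preset 0.01. For the other lists called it ran from 0.034 (cartilage) to 0.751 (airway epithelium). A correlation above the preset therefore does not account for the lost adrenomedullin call. Leaving out 1 library gave 6 to 12 higher and 2 to 5 lower lists. White adipocyte, airway, adrenomedullin and cartilage lists passed in all 5 of these fits. The test direction of 15 lists that had not passed turned without 1 library or more. Some passed in opposite directions. ER chaperones were higher without chow replicate 8 and lower without chow replicate 2 or high fat diet replicate 2. Skeletal muscle and erythroid were higher without chow replicate 2 and lower by the test without chow replicate 8. The erythroid mean there was still above 0, at 0.385. Cell cycle was higher without high fat diet replicate 2 and lower without high fat diet replicate 10. These are among the 15 lists that turned. The mean log2 fold change of their members ran from -0.198 to 0.291 for ER chaperones, -0.082 to 0.198 for epithelial to mesenchymal transition, -0.315 to 0.199 for brown adipocyte, -0.152 to 0.106 for B and plasma cell, -0.467 to 0.424 for T and NK cell, -0.098 to 0.076 for thyroid differentiation, -0.222 to 0.35 for cell cycle, -0.073 to 0.246 for fibroblast and matrix, -0.071 to 0.059 for oxidative phosphorylation, -0.017 to 0.319 for macrophage, -0.869 to 0.721 for neutrophil, -0.543 to 1.186 for skeletal muscle, -0.166 to 1.975 for erythroid, 0.047 to 0.367 for fatty acid oxidation and 0.021 to 0.17 for the integrated stress response. With fry the direction also turned for epithelial to mesenchymal transition (0.045), oxidative phosphorylation (0.016) and B and plasma cell (0.042), the last also with no filter (0.045) and with DESeq2 (0.043), and with limma-voom it turned for cell cycle (-0.008) and neutrophil (-0.101); the cause was not tested. Scaling moved the median log2 fold change of all genes by under 0.1, from 0.007 with RLE to 0.014 with upper-quartile factors. No paired analysis was possible because the groups share only 1 number. The alternatives planned for a table without counts were not run, since counts were given. A gene at 1 CPM has about 50 counts in a library of this depth. In the simulation edgeR recovered 42% of 2-fold and 95% of 4-fold changes. The changed genes there left out those of low expression, so these shares do not cover genes near 1 CPM.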

Other observations

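All tests in this part were chosen only after the result was seen, except the splits of the libraries and the first form of the test of the genes next to Adm2. Of 16 genes of the circadian clock looked at, the activators Npas2, Arntl and Clock had log2 fold changes of -0.68, -0.47 and -0.39, while Ciart had 1.05, Per2 0.72, Dbp 0.45, Cry1 0.44, Cry2 0.41 and Tef 0.36. Nr1d1 was at -0.25, Per1 at -0.15 and Nr1d2 at 0.10, Per3, Hlf, Bhlhe40 and Bhlhe41 lay between 0.29 and 0.35, and none of the 16 passed over all genes in edgeR, while DESeq2 called Per2 and Dbp. The labels give no time of dissection, on which clock genes depend, and without chow replicate 2 Npas2 and Arntl stood at -0.26 and -0.22. Among heat shock genes Hspa1b had 0.67, Hspa1a 0.65, Hspa8 0.46 and Hsph1 0.42, each above both chow libraries in every high fat diet library, while Hspb1 had 0.37, Hsp90aa1 0.26, Hspd1 0.19, Dnajb1 0.03 and Hspe1 0.01. None of these passed in edgeR, and DESeq2 called Hspa1b (adjusted p = 0.00601), Hspa1a (adjusted p = 0.0185) and Hspa8 (adjusted p = 0.0228). Surfactant genes were also measured: Sftpb at 2150 ± 540 CPM (SD, n = 2) on chow and 3173 ± 770.1 CPM (SD, n = 3) on the high fat diet, and Sftpd at 862 ± 128 and 1383 ± 150.0 CPM. Sftpd had a log2 fold change of 0.68, Sftpc 1.46 and Sftpa1 0.32; none passed in edgeR, and DESeq2 called Sftpd (adjusted p = 0.00494). Without high fat diet replicate 10, which had the highest values, Sftpc stood at 0.75 and Sftpa1 at -0.15.

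Pairs of near-identical copies differed between single libraries. Atp6v0c had 58 counts in high fat diet replicate 2 and 2444 to 3250 elsewhere, while its copy Atp6v0c-ps2 had 2566 counts there and 3 or 4 elsewhere, so the sum stayed between 2447 and 3254. Gm14434 and Gm4724 had 792 and 216 counts in chow replicate 2 and 147 and 739 in chow replicate 8. Amd1 had 376 counts in chow replicate 8 and 1 in every other library, so its calls in edgeR without chow replicate 2 and in DESeq2 set that library against the rest.

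High fat diet replicate 10 had 133 genes more than 2-fold above every other library, against 3 to 7 in the others, among them Muc5b at 4638 CPM, Trf, Smoc1, Irs4 and Hbb-b1. Muc5b stood 46.6 times above the median of the other 4 libraries, and the other 9 airway genes were all higher too, by a median factor of 2.19 and at most 7.82, for Muc5ac. Airway tissue carried over and a change in the gland cannot be told apart by these factors, because the airway genes have a baseline in every library (Bpifa1 at a median of 629 CPM) and no level for pure airway tissue was measured; the rule first set, which counted the lower factors against airway tissue, was dropped for this reason after they were seen. Fewer thyroid cells cannot be told apart either: of 18 thyroid genes, 10 (Tg, Slc26a7, Dio1 and Iyd among them) were below both other high fat diet libraries and 5 (Slc5a5, Nkx2-1, Foxe1, Hhex and Glis3) above both, where no difference gives 6 each, and a first rule that counted the 5 against it was dropped after they were seen. A difference of the tissue itself or of its handling stays open and was not tested.

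The white adipocyte list was lower on the high fat diet, with Cidec, Cfd and Plin1 below the chow libraries in every high fat diet library. Fewer adipocytes in the dissected tissue would lower adipocyte-restricted genes by 1 common factor. A chi-square test of heterogeneity treats genes as independent, though these share libraries and the list had an estimated correlation of 0.41, so its p-values are rough. Over Adipoq, Plin1, Cfd, Cidec, Retn and Lep, approximate also with so few libraries, the chi-square test gave p = 0.00388. As first set, the rule counted this value alone against fewer adipocytes; it was changed after the chi-square test was seen to give p = 0.121 without Lep, the 1 gene above 0, while leaving out any other gene gave 0.00189 to 0.00985. Few reads are no reason to leave out Lep alone, as Retn has fewer, and without both, the genes under 2 CPM in both groups, the chi-square test gave p = 0.0668. A smaller number of adipocytes and a change within them cannot be told apart, because the answer rests on Lep and on this later choice, and an effect of the diet itself stays open.

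The Adm2 difference was weighed against reads running in from its neighbours and against a broad integrated stress response, which is known to induce Adm2. A broad response in which the list moves by about as much as Adm2 was not seen: the 18 members had a median of 0.097 with an SD of 0.268, below the bound of 1.02 set for it, and a response to which Adm2 alone is more sensitive was not tested. Sbf1 and Lmf2 had log2 fold changes of 0.164 and -0.03, and Miox was not measured. A gene's own level does not measure reads beyond its ends. By position and strand, Sbf1 and Miox are transcribed away from Adm2, which argues against reads running past their ends into it. Lmf2, beyond Miox on the opposite strand, is transcribed toward Adm2. Reads from Lmf2 cannot be told apart, because whether counting used strand is not given. The first form of this test used the measured neighbours alone and would have counted their log2 fold changes against reads from any neighbour. It was changed after those values were seen. An effect of the diet on Adm2 stays open as a hypothesis.

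The 10 splits of the 5 libraries into 2 and 3 are too few for a share under 0.05. At an adjusted p under 0.10 in edgeR the real split gave 10 genes and the highest other split 11, and in DESeq2 96 and 139, so that 2 splits, the real one included, gave as many genes by either tool. The higher one set chow replicate 8 and high fat diet replicate 10 against the rest, the libraries that the principal components set apart, and gave 7 genes under 0.05 in edgeR, where the real split gave 0 and the split that set high fat diet replicates 9 and 10 against the rest gave 4. At an unadjusted p under 0.05 in edgeR the real split gave 855 genes and the others 222 to 1094, with 1094, 1038 and 996 in the 3 that were higher.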
